A study of Mus musculus with 4 samples.

How the data were processed

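RNA from cochleae of postnatal day 10 mice was measured by RNA sequencing in 2 wild-type and 2 Zbtb20 knockout libraries. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table per library with FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library), per the file headers, rounded to 2 decimals. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm10 are named without their roles, per the submitters' processing notes. Whether the library preparation or the counting used strand is not given in the sources used here, so genes that overlap on either strand can share fragments. RSEM divides fragments that match several genes between them by estimation, so values of near-identical paralogs are uncertain.

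Each table had 20777 rows named by NCBI gene ID. Of these, 2961 held no value in any library, which left 17816 genes, 201 of them listed at 0 in all 4 libraries. An FPKM of 0 was read as listed at 0, since the tables give no counts. A repeated FPKM column in each table (4 per-sample columns) was not used. Symbols were looked up by gene ID in a RefSeq gene reference, in which 20705 IDs matched, because 26 symbols in the tables had become dates and 2 were blank. Gene positions, strands and shared exon bases were looked up by symbol in GENCODE vM21 on GRCm38 (the assembly of mm10).

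The plan, fixed before the data were examined, named a test for counts first and limma on log2(FPKM + 1) where only FPKM was deposited. The tables held FPKM, so the second test was used and not edgeR or DESeq2. Genes with a mean of at least 0.5 FPKM over the 4 libraries were kept (13966), and limma 3.58.1 in R 4.3.3 was fitted with genotype as the 1 term and an intensity trend in the empirical Bayes step. P-values were adjusted by the Benjamini-Hochberg method, two-sided, with a threshold of 0.05. A fold change is the knockout minus the wild-type mean of log2(FPKM + 1) unless a ratio of mean FPKM is named, and the pseudocount of 1 understates the change of low genes. Errors are SE for log2 fold changes and SD for FPKM, with 2 libraries per group.

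Gene lists for 33 cell types, pathways and neighbouring tissues were fixed before the data were examined. Of 459 members 440 had a value and 373 were tested, and 1 list, of mitochondrially encoded genes, had no tested member. The other 32 lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated for each list, and the rotation test fry was run in its directional and mixed forms. Of the 32 lists 18 passed with the preset correlation, 4 higher and 14 lower, and 0 with an estimated one (lowest adjusted p 0.35). The estimate rests on 4 libraries, and camera then gave the same adjusted p of 0.35 to the myelin list (median -2.34) and the hair bundle list (-0.12). Benjamini-Hochberg adjustment can give lists with unlike p-values the same adjusted p, and the power of that form was not measured. What not passing it means for a list is therefore open. The estimated correlations differed from the preset one, at 0.77 for the myelin list, 0.99 for the muscle list and -0.02 for the hair bundle list. The preset correlation stays an assumption. Some genes are in more than 1 list. Named genes are Zbtb20 first, then the 12 with the largest positive and the 12 with the largest negative log2 fold change among called genes at a mean of at least 1 FPKM whose knockout libraries both lay beyond both wild-type libraries, then up to 4 members with the smallest p of each list. Further list members named beside them, Gm19345 and Afp were chosen after their values were seen. Some genes that the rule names are counted but not reported here by name.

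The tables give no totals of fragments, so the depth was estimated from the FPKM. An FPKM multiplied by transcript length and depth is a whole number of fragments where fragments were counted whole, and the depth was sought that made most low values (up to 6.5 fragments) whole within 0.15. This used 5158 genes with 1 transcript of 300 to 2500 bases. Between 483 and 519 values per library entered, and 71.4% to 73.6% came out whole where chance gives 30%. Simulated depths of 12000000, 20000000 and 35000000 fragments were returned as 11950000, 19950000 and 34800000. Taking 100, 150 or 200 bases off each transcript made fewer values whole (53.9% to 68.2%) and gave 19500000 to 23200000 fragments. With 250 bases off, the estimate was 50950000 and 53400000 from 60 and 70 values in the wild type and 22100000 and 24350000 in the knockout, and it was not used. The share of whole values was too low for the fragments to be treated as recovered counts. FPKM is relative to the fragments of each library, so a transcript that takes a larger share lowers the others. The 10 highest genes took 8.8% to 9.5% of the summed FPKM.

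Replicates were compared before they were averaged. Between 32 and 56 genes had identical FPKM in any pair of libraries, and no pair was a copy of another. The fit was tested on simulated libraries of the same number with 13966 genes, of which 67 changed 2-fold, 67 4-fold and 66 8-fold. It called 86.6%, 100% and 98.5% of these, with 11 false calls, and 0 genes when none was changed. With 1 list shifted, 1 list passed by camera. The changed genes were drawn from the more abundant tested genes, and the change was added on the log2(FPKM + 1) scale. The simulated noise was independent between genes and libraries, while real libraries of the same number deviated together (correlation 0.4). These rates therefore need not hold for the real libraries.

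The alternatives planned were no filter on low values, the replicate number as a block, leaving out each library, a pseudocount of 0.1, an adjusted p under 0.01, a minimum change of 2-fold, an estimated correlation and fry. Rescaling by each library's median of ratios or to equal sums of FPKM, a filter of 1 FPKM in at least 2 libraries, and the pseudocount of 0.1 for the lists were added after the data were seen. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.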

Results

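RNA from mouse cochleae at postnatal day 10 was sequenced in 4 libraries, 2 from wild-type and 2 from Zbtb20 knockout mice of the C57BL/6 strain. Zbtb20 encodes a zinc finger transcription factor, and the comparison asks how cochlear transcripts differ in the knockout. The genotype labels give F/F at Zbtb20 with a cre driver for the knockout and +/+ with a cre driver for the wild type. The libraries carry the replicate numbers 2 and 3 in each genotype. Nothing in the labels says that they came from separate animals, so p-values measure only the spread between these libraries. Muscle genes summed to 603.1 and 8.5 FPKM in wild-type replicates 2 and 3. The 4 tested sex-linked genes, all on chromosome Y, summed to 17.7 and 28.3 FPKM in wild-type replicates 2 and 3. They summed to 55.6 and 27.6 FPKM in knockout replicates 2 and 3, so the amount of male RNA differed between libraries. Libraries of the same genotype were therefore not repeats of the same RNA, but whether their spread is that between animals is not known. Values were deposited as FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), which summed to 405144 and 391808 in wild-type replicates 2 and 3 and to 400487 and 398113 in knockout replicates 2 and 3. Between 12933 and 13008 genes were above 1 FPKM in each library. The steps between low FPKM values placed the depth near 17950000 and 18600000 fragments for the wild type and 17900000 and 19400000 for the knockout, a relative depth of 1.0 to 1.08. The absolute figure depends on the transcript length assumed, and was 19500000 to 21150000 with 100 bases taken off each transcript. Of 12974 expressed genes, 212 differed over 2-fold between the wild-type replicates, and 62 of 12985 did so between the knockout replicates. Between libraries of different genotype 315 to 468 genes differed that much.

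Zbtb20 was measured at 10.94 and 10.67 FPKM in the wild-type libraries and at 7.35 and 7.41 FPKM in the knockout libraries. It lies on chromosome 16 from 42875881 to 43642602 on the plus strand of GRCm38. Its level fell by 0.49 ± 0.08 (SE, n = 2 per group) on the log2(FPKM + 1) scale, with a wild-type mean 1.46 times that of the knockout (adjusted p = 0.0394, limma). A gene-level FPKM counts fragments from every exon, including any outside the deleted part, which the labels do not name. In which cochlear cells the part was deleted was not measured, and cells that kept it would add fragments too. The limma call for Zbtb20 was lost without wild-type replicate 2 (adjusted p = 0.0885), wild-type replicate 3 (0.083), knockout replicate 2 (0.316) and knockout replicate 3 (0.264), with log2 fold changes from -0.51 to -0.48, and without the filter on low values (0.0766).

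The knockout cochleae held more transcript of Ttr (34.4-fold), of 5 of 11 tested genes of strial pigment cells and of 5 of 13 of strial marginal cells, and less of all 16 tested genes of peripheral myelin and of the tectorial membrane gene Ceacam16 (14.5-fold). Of 13966 genes tested, 618 passed an adjusted p of 0.05 (limma), 333 of them higher and 285 lower in the knockout, and 216 changed at least 2-fold. Rescaling each library by its median of ratios turned that split to 243 higher and 355 lower. In all 618 called genes both knockout libraries lay beyond both wild-type libraries, as they did in 7675 (55%) of the tested genes, where chance gives 33.3%. At an unadjusted p under 0.05 there were 3078 genes. The calls rest on all 4 libraries: Ttr was the 1 gene past the threshold without knockout replicate 2 (log2 fold change 4.84, adjusted p = 0.0461) or without knockout replicate 3 (5.07, adjusted p = 0.0356), when 1615 and 1782 genes had an unadjusted p under 0.05. Without wild-type replicate 2 or 3 there were 534 and 580 calls, of which 403 and 373 were among the 618. Without the filter on low values there were 266, 247 of them shared, and 47 of the 74 called genes named by the fixed rule kept their call.

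**Figure D1:**
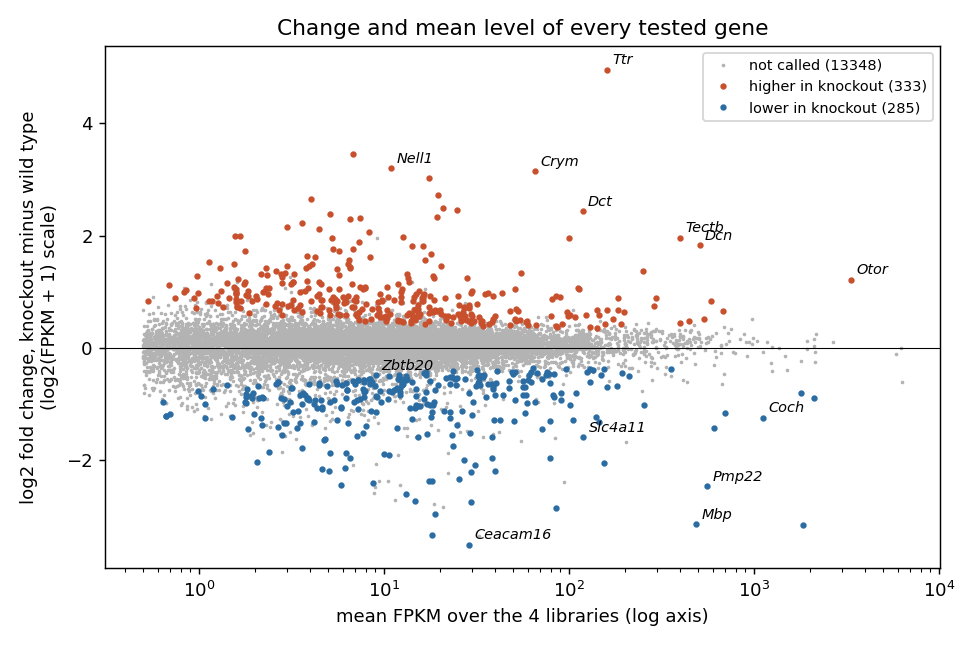
Log2 fold change (knockout minus wild type, log2(FPKM + 1) scale) against the mean FPKM over the 4 libraries on a log axis, with 1 point for each of the 13966 tested genes. Orange-red points are the 333 genes called higher and blue points the 285 called lower, with Ttr at 4.96 and Ceacam16 at -3.51 as the extremes.

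Ttr, which encodes transthyretin, a carrier of thyroxine and retinol, rose from 9.05 ± 0.693 to 311.8 ± 35.8 FPKM (SD, n = 2 per group), a log2 fold change of 4.96 ± 0.1 (adjusted p = 0.000516, limma; chromosome 18, 20665280 to 20674321). Crym, the gene of a cytosolic thyroid hormone binding protein, rose 9.48-fold from 12.48 ± 1.29 to 118.2 ± 9.55 FPKM (adjusted p = 0.0014; chromosome 7, 120186380 to 120202111). The aldehyde oxidase gene Aox2 went from 0.295 ± 0.0778 to 13.3 ± 1.7 FPKM, and Nell1, which encodes a secreted glycoprotein, rose from 1.35 ± 0.0707 to 20.58 ± 0.417 FPKM. Krt23, a keratin gene, rose 10.4-fold, and Elf5, which encodes an ETS transcription factor, rose from 0.385 ± 0.0212 to 7.73 ± 0.467 FPKM. The heparanase gene Hpse rose 6.44-fold, the carbonic anhydrase gene Car9 9.47-fold and Slc16a11, of the monocarboxylate transporter family, 5.7-fold. The neighbouring claudin genes Cldn24 and Cldn22 on chromosome 8 rose 7.79-fold and 6.09-fold. All exon bases of Cldn22 lie within Wwc2 on the other strand, and reads from the 2 genes cannot be separated unless strand was used, which the sources used here do not state. Dct, which encodes the melanin enzyme dopachrome tautomerase, completed the 12 largest rises on the log2(FPKM + 1) scale at 36.24 ± 2.26 and 200.7 ± 11.4 FPKM. Adjusted p for these 12 genes ran from 0.000516 to 0.00448. Except for Ttr, none passed without knockout replicate 2 (lowest adjusted p 0.0875) or without knockout replicate 3 (0.08).

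**Figure D2:**
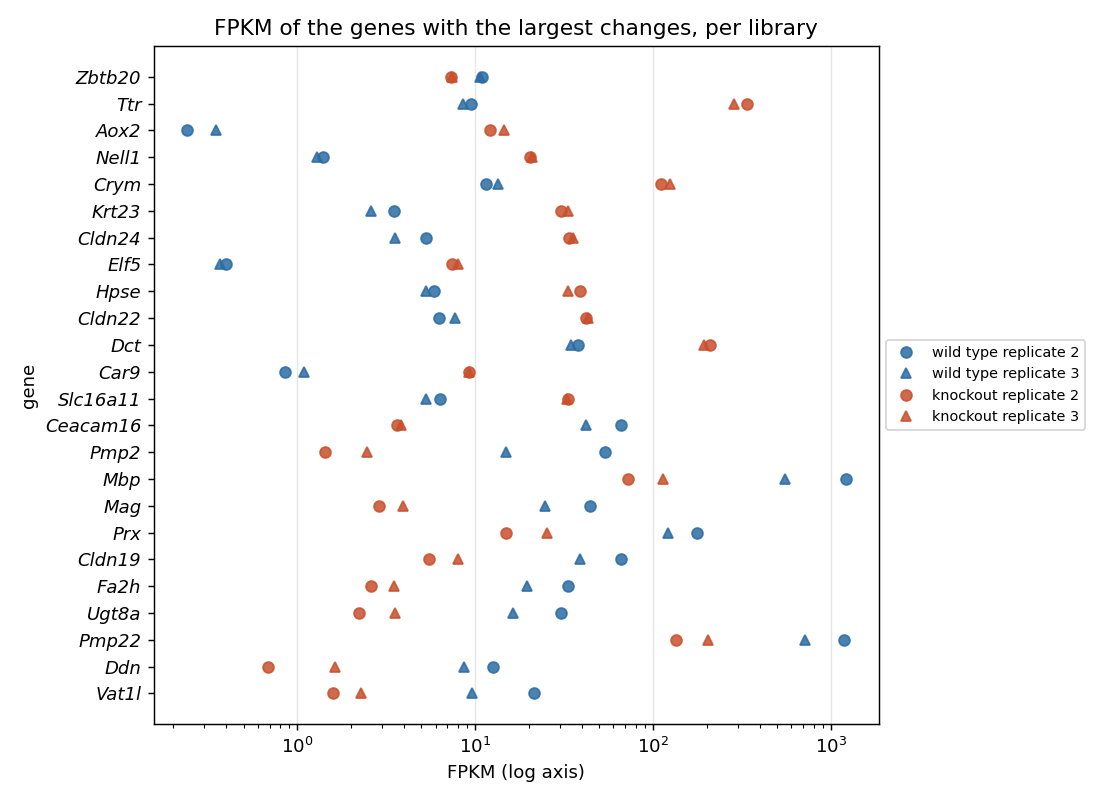
FPKM on a log axis in each library for Zbtb20, the 12 genes with the largest rise and the reported genes among the 12 with the largest fall on the log2(FPKM + 1) scale, with wild type in blue, knockout in orange-red, circles for replicate 2 and triangles for replicate 3. Ttr sits at 9.54 and 8.56 FPKM in the wild type and at 337.1 and 286.5 FPKM in the knockout, and Pmp22 at 1183 and 715.5 FPKM against 134.9 and 203.3 FPKM.

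Genes of Schwann cells, the glia that wrap peripheral axons in myelin, fell together. All 16 tested members of the list fell, both over all genes and adjusted over the list alone, with a median log2 fold change of -2.34. Mbp, the myelin basic protein gene, was at 881.3 ± 465 FPKM in the wild type and 93.43 ± 29.9 FPKM in the knockout (SD, n = 2; 9.43-fold lower, adjusted p = 0.0227, limma; chromosome 18, 82475146 to 82585637). Without wild-type replicate 2, a library with skeletal muscle transcripts, Mbp was 5.91-fold lower (adjusted p = 0.0116). Pmp22, another gene of compact myelin, fell 5.61-fold and the periaxin gene Prx 7.41-fold. Egr2, the gene of the transcription factor that drives Schwann cell myelination, went from 10.42 ± 0.544 to 2.12 ± 0.368 FPKM (log2 fold change -1.88 ± 0.12, adjusted p = 0.00562). Mag, Cldn19, Fa2h and Ugt8a were also among the 12 largest falls on the log2(FPKM + 1) scale, as was Pmp2 (-3.34 ± 0.57), of which 86.9% of exon bases are shared with the transcript model Gm37389 on the same strand. Ddn and Vat1l, also among them, were at -2.44 ± 0.27 and -2.41 ± 0.36. Summed FPKM of the myelin list was 7534 and 4271 in wild-type replicates 2 and 3 and 602.9 and 979.2 in knockout replicates 2 and 3. The list stood apart from other genes by camera (adjusted p = 8.34e-24). It did not pass camera with an estimated correlation (adjusted p = 0.35) or directional fry (adjusted p = 0.0605), and it passed mixed fry (adjusted p = 0.0175). The correlation estimated for the list was 0.77, against the preset 0.01, and the power of camera with an estimated correlation was not measured. All 16 members were called lower without wild-type replicate 2 and without wild-type replicate 3, and 0 without knockout replicate 2 or knockout replicate 3, when camera still gave adjusted p = 2.11e-24 and 9.94e-25.

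Genes of the stria vascularis, the epithelium that secretes potassium into the endolymph, rose in part. In the marginal cell list 5 of 13 tested members rose and 0 fell, or 8 and 1 adjusted over the list alone. Kcne1 and Kcnq1, subunits of the channel that carries potassium into the endolymph, rose by 1.56 ± 0.09 and 0.85 ± 0.1 on the log2 scale (adjusted p = 0.00448 and 0.0194, limma). Bsnd, which encodes the chloride channel subunit barttin, rose 4.4-fold, and the nuclear receptor gene Esrrb rose from 4.53 ± 0.523 to 20.74 ± 3.25 FPKM. The cotransporter gene Slc12a2 had a log2 fold change of 0.01 ± 0.11 (adjusted p = 0.981). For intermediate cells, the melanocytes of the stria, 5 of 11 members rose and 1 fell, or 6 and 1 adjusted over the list alone. Dct, Slc45a2, Tyr, Mlana and Pmel, all genes of melanin synthesis or of the melanosome, rose, with Tyr, the tyrosinase gene, at 1.55 ± 0.0566 and 11.58 ± 0.516 FPKM. Kit, the gene of the receptor on which melanocytes depend, fell by 0.79 ± 0.13 (adjusted p = 0.0412). Mitf and Sox10, transcription factor genes of the same cells, were at 0.16 ± 0.11 and -0.15 ± 0.12. Of 10 members of the basal cell and tight junction list 1, Cldn11, rose (0.59 ± 0.1, adjusted p = 0.0382) and 0 fell, or 2 and 1 adjusted over the list alone. Cldn11 did not pass after median-of-ratios rescaling (0.52, adjusted p = 0.0656) or without any 1 library (adjusted p = 0.0526 to 0.28). Camera gave adjusted p = 0.00362, 0.000355 and 0.773 for the marginal, intermediate and basal lists, and with an estimated correlation adjusted p = 0.52, 0.35 and 0.822. The basal list had a median of 0.07 and a camera direction below the other genes. With either knockout library left out (replicate 2 or replicate 3), 0 members of the 3 lists were called, and without wild-type replicate 3 the intermediate list had 6 higher and 0 lower and the basal list 0 higher and 1 lower.

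**Figure D3:**
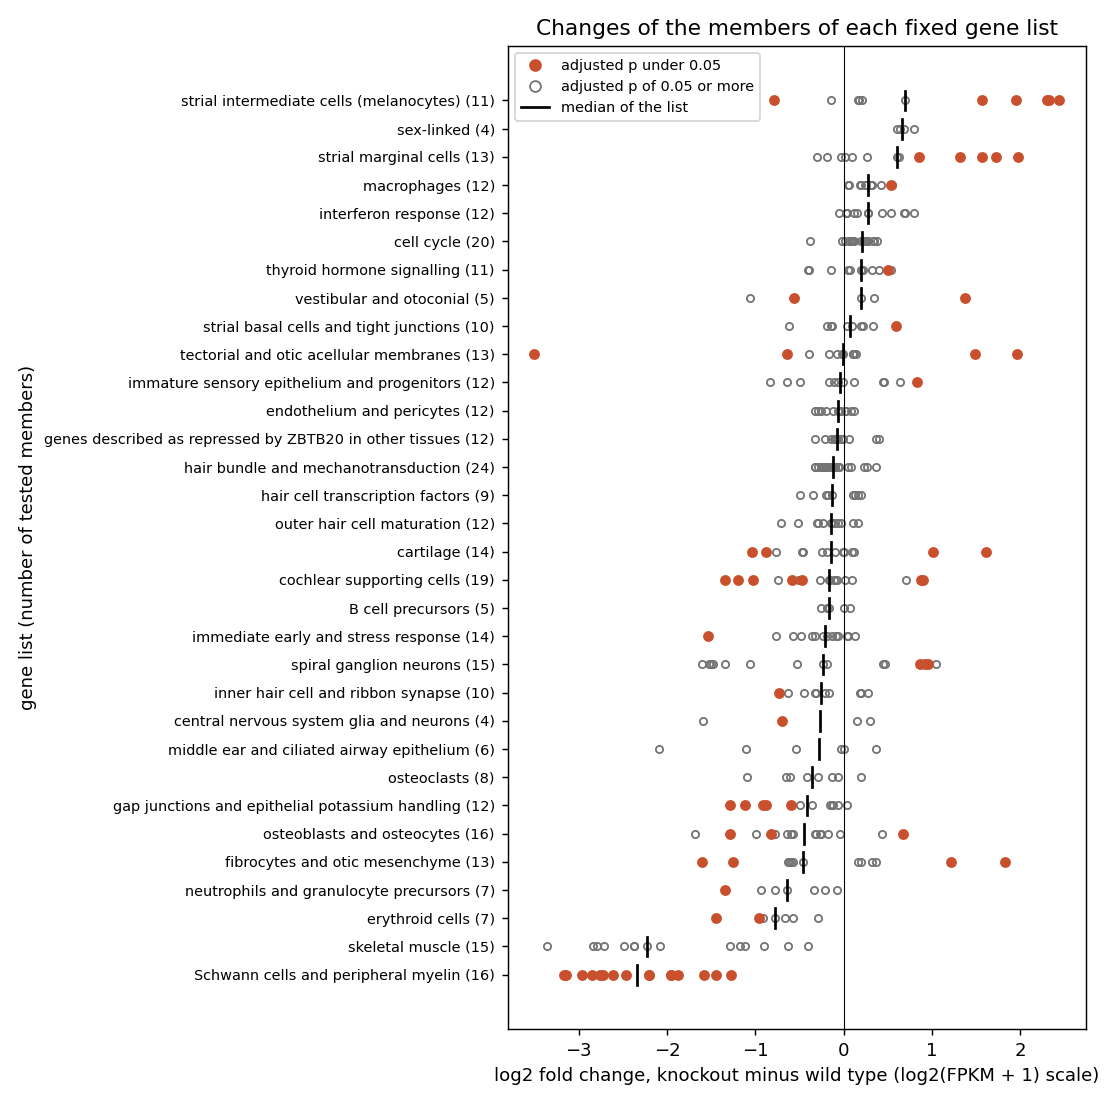
Log2 fold change of each tested member of the 32 gene lists, with filled points for an adjusted p under 0.05 (limma) and a bar at the median of each list, ordered by that median. The myelin list lies apart with all 16 members called and a median of -2.34, and the intermediate cell list has the highest median, 0.69.

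In the list for the tectorial membrane, the acellular matrix over the hair cells, 2 of 13 tested members rose and 2 fell, or 2 and 3 adjusted over the list alone. Ceacam16, which encodes a tectorial membrane glycoprotein, fell 14.5-fold from 54.14 ± 17.5 to 3.73 ± 0.156 FPKM (log2 fold change -3.51 ± 0.22, the lowest of all called genes on the log2(FPKM + 1) scale, adjusted p = 0.00486, limma; chromosome 7, 19852097 to 19861299). Of its exon bases 23.2% overlap Gm19345 on the other strand, which fell by 1.43 ± 0.1. Otogl, the otogelin-like gene, fell by 0.64 ± 0.08. Tectb and Tecta, which encode the tectorins, rose from 161.6 ± 4.36 to 635.3 ± 105 FPKM and from 2.825 ± 0.233 to 9.9 ± 2.73 FPKM. The collagen gene Col2a1 was at 6160 and 6392 FPKM in the wild type and 6516 and 5944 FPKM in the knockout. Camera gave adjusted p = 0.406 for the list, and 0.812 with an estimated correlation. Without knockout replicate 2 or 3 no member was called (0 of 13), and without wild-type replicate 3 Otogl had adjusted p = 0.0557.

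Supporting cell genes, from the cells around the hair cells, were lower in 5 and higher in 2 of 19 tested members, or 7 and 2 adjusted over the list alone. Emid1 fell from 137.2 ± 9.81 to 66.59 ± 1.86 FPKM (adjusted p = 0.00752, limma). Ngfr, the neurotrophin receptor gene expressed in pillar cells and also in Schwann cells, fell 3.02-fold (adjusted p = 0.0116), and Fabp3, Slc1a3 and the cell cycle inhibitor gene Cdkn1b fell by 1.2 ± 0.17, 0.59 ± 0.1 and 0.47 ± 0.08. The endothelin receptor gene Ednrb and the Notch target Hey2 rose 1.92-fold and 1.98-fold. Sox2, a transcription factor gene of these cells, was at 0.09 ± 0.14. Camera placed the list below other genes (adjusted p = 0.000318; adjusted p = 0.35 with an estimated correlation). The peripheral myelin genes, which Schwann cells share with Ngfr, fell in the same libraries. Leaving out knockout replicate 2 or 3 left 0 calls, and leaving out wild-type replicate 2 or 3 left 4 lower.

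In the list for gap junctions and epithelial potassium handling, through which potassium leaves the hair cell region, 5 of 12 tested members fell and 0 rose, or 7 and 0 adjusted over the list alone. Kcnj16, an inward rectifier potassium channel gene, fell from 60.34 ± 1.75 to 24.16 ± 2.28 FPKM, and Slc26a4, which encodes the anion exchanger pendrin, fell from 36.43 ± 1.63 to 16.23 ± 0.792 FPKM (adjusted p = 0.00629 and 0.0067, limma). Kcnk5, P2rx2 and the water channel gene Aqp4 fell by 0.91 ± 0.12, 0.6 ± 0.08 and 0.88 ± 0.13. The connexin genes Gjb2 and Gjb6 were at -0.16 ± 0.08 and -0.36 ± 0.07 and did not pass. Camera gave adjusted p = 5.08e-08, and adjusted p = 0.35 with an estimated correlation. There were 3 calls without wild-type replicate 2, 4 without wild-type replicate 3 and 0 without either knockout library.

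In the list for fibrocytes of the spiral ligament and otic mesenchyme, 2 of 13 tested members rose and 2 fell, or 4 and 5 adjusted over the list alone. Slc4a11, which encodes a membrane transporter, fell from 180.4 ± 10.6 to 58.86 ± 2.27 FPKM (adjusted p = 0.00245, limma), and Coch, the gene of the extracellular protein cochlin, from 1573 ± 64.3 to 662 ± 80.3 FPKM (adjusted p = 0.00947). Dcn, the gene of the proteoglycan decorin, rose from 221.5 ± 2.55 to 795.1 ± 104 FPKM, and Otor, which encodes the secreted protein otoraplin, from 2014 ± 138 to 4658 ± 13.5 FPKM. The list did not stand apart by camera (adjusted p = 0.346; 0.679 with an estimated correlation). Its median of -0.46 was 0.17 without wild-type replicate 2. There were 0 calls without knockout replicate 2 or 3, and 4 lower without wild-type replicate 3.

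Hair cell genes showed few single changes. In the hair bundle and mechanotransduction list 0 of 24 tested members passed (limma, 1 higher and 2 lower at an unadjusted p under 0.05), and none adjusted over the list alone. Its median was -0.12, and Myo7a and Pcdh15, which encode a stereocilia myosin and a tip link protein, were at -0.29 ± 0.11 and -0.32 ± 0.13. Of 12 outer hair cell genes 0 passed, with 4 lower at an unadjusted p under 0.05 and 1, the acetylcholine receptor gene Chrna9 (-0.52 ± 0.11), lower adjusted over the list alone. Slc26a5, the gene of the motor protein prestin, was at 6.845 ± 0.332 and 5.43 ± 0.424 FPKM. Among 10 inner hair cell and ribbon synapse genes 1, the calcium pump gene Atp2a3, fell (-0.73 ± 0.11, adjusted p = 0.0341), also adjusted over the list alone, while Otof, the otoferlin gene, was at -0.63 ± 0.17 (adjusted p = 0.123). Camera placed these 3 lists below other genes (adjusted p = 0.00305, 0.00491 and 0.0238), with adjusted p = 0.35, 0.35 and 0.512 with an estimated correlation. The bundle list had adjusted p = 0.0538 without knockout replicate 3, and the inner hair cell list 0.111 without wild-type replicate 3 and 0.0718 after median-of-ratios rescaling. The call for Atp2a3 was lost without any 1 of the 4 libraries (adjusted p = 0.0649 to 0.211). Of 9 hair cell transcription factor genes 0 passed (3 lower at an unadjusted p under 0.05), none adjusted over the list alone, with Pou4f3 at -0.5 ± 0.16 and camera adjusted p = 0.202.

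Among spiral ganglion neuron genes 3 of 15 tested members were called higher and 0 lower, or 4 and 0 adjusted over the list alone. Ntrk3, the receptor gene for neurotrophin-3, rose from 9.91 ± 0.495 to 20.05 ± 1.32 FPKM (adjusted p = 0.0107, limma), and Syt1, which encodes a synaptic vesicle protein, rose by 0.92 ± 0.13. Other members differed widely between the libraries of each genotype. Tubb3, Nefl, Nefm, Nefh, Snap25 and Calb2 had log2 fold changes of -1.61 to -1.06 and were lower in the knockout at each replicate number. None of them passed over all genes, nor did Stmn2, Gata3 and Rbfox3, at 1.05, 0.47 and 0.44. With the replicate number as a block, 4 members were called higher and 6 lower. The labels do not say that the numbers mark shared animals or days. Nefl, a neurofilament gene, was at 29.81 and 85.33 FPKM in wild-type replicates 2 and 3 and at 8.59 and 32.05 FPKM in knockout replicates 2 and 3, and Snap25 at 15.24, 57.68, 5.06 and 23.18 FPKM. Neither passed (adjusted p = 0.282 and 0.394). The summed FPKM of the list was 283.6, 607.7, 214.7 and 336.4 in the same order, and camera gave adjusted p = 0.584 (0.842 with an estimated correlation). In the list for central nervous system glia and neurons 1 of 4 tested members, the proteoglycan gene Bcan, fell (-0.7 ± 0.07, adjusted p = 0.0114), also adjusted over the list alone, and camera gave adjusted p = 0.202. Without knockout replicate 2 or 3, 0 genes of either list were called.

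**Figure D4:**
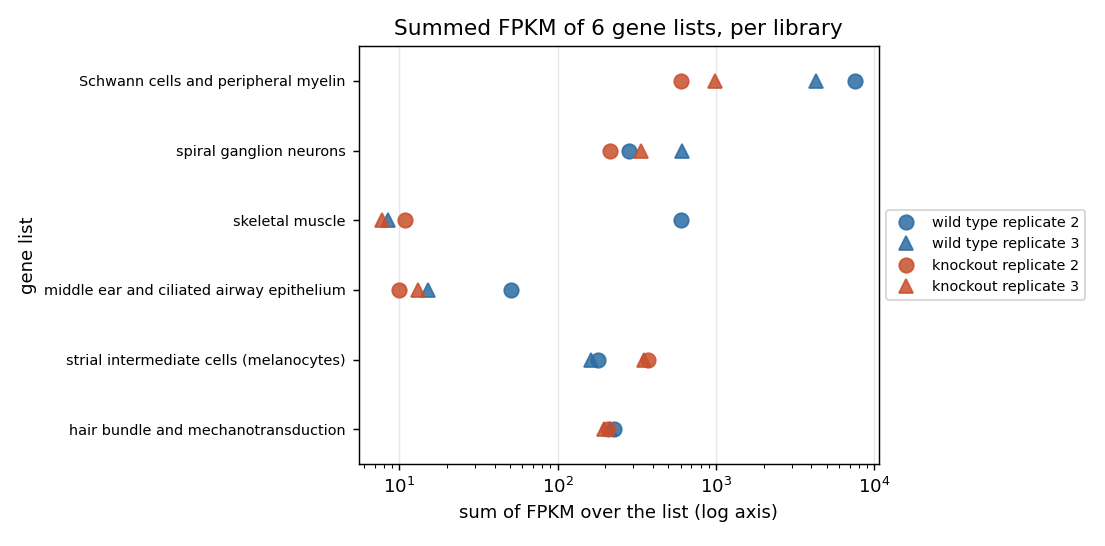
Summed FPKM, on a log axis, of 6 gene lists in each library, with wild type in blue, knockout in orange-red, circles for replicate 2 and triangles for replicate 3. The muscle list stands at 603.1 in wild-type replicate 2 and at 7.8 to 10.8 in the other libraries, and the myelin list at 4271 or more in the wild type and 979.2 or less in the knockout.

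Transcripts of neighbouring tissues also differed between libraries. Wild-type replicate 2 held skeletal muscle RNA, with the muscle actin gene Acta1 at 130.8 FPKM there and at 0.11, 0.38 and 0 in wild-type replicate 3 and knockout replicates 2 and 3. Of 15 muscle genes 0 passed (limma, 0 at an unadjusted p under 0.05), none adjusted over the list alone, and the camera call for the list (median -2.23, adjusted p = 0.00022; 0.539 with an estimated correlation) was lost without that library (-0.03, adjusted p = 0.856). The airway gene Bpifb1 was also highest there, at 26.63 FPKM against 0 to 0.34 FPKM, in a list for middle ear and ciliated airway epithelium of which 0 of 6 passed (1 lower at an unadjusted p under 0.05, none adjusted over the list alone; camera adjusted p = 0.202). Of 16 osteoblast and osteocyte genes 1 rose and 2 fell, or 2 and 3 adjusted over the list alone. Mepe and Sost, genes of osteocytes, fell by 1.29 ± 0.13 and 0.82 ± 0.14, and Spp1, the osteopontin gene, rose by 0.67 ± 0.11, a call lost after median-of-ratios rescaling (0.59, adjusted p = 0.0567) and without wild-type replicate 3 (0.53, adjusted p = 0.0513). Camera gave adjusted p = 6.93e-05 (0.432 with an estimated correlation). Osteoclast genes had 0 of 8 past the threshold (1 lower at an unadjusted p under 0.05, none adjusted over the list alone), with a camera adjusted p of 0.0162 (0.512 with an estimated correlation) that was 0.211 without wild-type replicate 2. Without wild-type replicate 3, which leaves the library with muscle RNA as the wild type, 14 muscle, 3 osteoclast and 2 middle ear genes were called lower. Cartilage genes split, 2 of 14 higher and 2 lower, or 2 and 4 adjusted over the list alone: the matrix genes Matn1 and Snorc rose 3.62-fold and 3.13-fold, and Acan and Chad fell by 1.04 ± 0.1 and 0.88 ± 0.09. Camera gave adjusted p = 0.0497 (0.52 with an estimated correlation), and 0.26 without wild-type replicate 2, 0.0673 without knockout replicate 2, 0.0812 without knockout replicate 3, 0.119 after median-of-ratios rescaling and 0.0525 without the filter. Without either knockout library 0 bone or cartilage genes were called.

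Few genes of blood and immune cells passed. Of 7 erythroid genes 2 fell, among them Slc4a1, which encodes a red cell membrane protein, 6.28-fold, and 3 fell adjusted over the list alone (camera adjusted p = 4.97e-05; 0.35 with an estimated correlation). Of 7 neutrophil genes 1, S100a9, fell 3.63-fold, with 3 lower adjusted over the list alone (camera adjusted p = 0.00032; 0.35 with an estimated correlation). Of 12 macrophage genes 1, the mannose receptor gene Mrc1, rose (0.53 ± 0.08), with 3 higher adjusted over the list alone (camera adjusted p = 0.00459; 0.432 with an estimated correlation). Interferon response genes had 0 of 12 past the threshold (limma, 4 higher at an unadjusted p under 0.05) and 3 higher adjusted over the list alone. Their camera adjusted p of 0.0372 (0.432 with an estimated correlation) was 0.0826 without wild-type replicate 3, 0.084 without knockout replicate 3 and 0.0516 without the filter, and 1 member was called higher without wild-type replicate 2. For 12 genes of endothelium and pericytes 0 passed (3 lower at an unadjusted p under 0.05, none adjusted over the list alone), with camera adjusted p = 0.0395 (0.512 with an estimated correlation) and 0.0705, 0.106 and 0.177 without wild-type replicate 2, wild-type replicate 3 and knockout replicate 2. Of 5 genes of B cell precursors 0 passed (0 at an unadjusted p under 0.05, none adjusted over the list alone; camera adjusted p = 0.213, and 0.00826 without the filter). Of 14 immediate early and stress genes 1, the nuclear receptor gene Nr4a1, fell 3.13-fold, also adjusted over the list alone, and the camera adjusted p of 0.00122 (0.52 with an estimated correlation) was 0.22 without wild-type replicate 2. Without knockout replicate 2 or 3, 0 of these genes were called. Without wild-type replicate 2 or 3 there was 1 erythroid call in place of 2, and Mrc1 had adjusted p = 0.0693 and 0.0751. Without wild-type replicate 2 there were 2 macrophage calls, and without wild-type replicate 3 there were 0, with 2 neutrophil and 2 immediate early calls.

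Lists chosen for the biology of ZBTB20 and of cochlear maturation showed few changes. The vestibular and sex-linked lists are given after them, and of 5 tested vestibular members 1 rose and 1 fell. Among 12 tested genes described in other tissues as repressed by ZBTB20, 0 passed (limma, 2 higher at an unadjusted p under 0.05), and 1, the nuclear receptor gene Nr2f1 at 0.36 ± 0.07, was higher adjusted over the list alone (camera adjusted p = 0.202). Afp, the alpha-fetoprotein gene that ZBTB20 represses in liver, was at 0.03 FPKM in knockout replicate 2 and listed at 0 in the other libraries. Of 20 cell cycle genes 0 passed (3 higher and 1 lower at an unadjusted p under 0.05, none adjusted over the list alone), with camera adjusted p = 0.123, and 0.0377 without wild-type replicate 2. Of 11 thyroid hormone signalling genes 1, the transporter gene Slc16a10, rose (0.5 ± 0.09, adjusted p = 0.048), or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.526). Slc16a10 did not pass without any 1 library (adjusted p = 0.0762 to 0.316) or after rescaling by median of ratios (0.0653) or to equal sums (0.0511). In the list for immature sensory epithelium and progenitors 1 of 12 members, the transcription factor gene Isl1, rose (0.83 ± 0.1, adjusted p = 0.0189), also adjusted over the list alone. Its median was -0.04, its mean 0.01 and its camera adjusted p 0.958, and it had 3 higher and 1 lower without wild-type replicate 2 and 1 of each without wild-type replicate 3. Of 5 vestibular and otoconial genes Oc90, the gene of the main otoconial matrix protein, rose from 139.5 ± 11.9 to 365 ± 66.1 FPKM and Otol1 fell by 0.56 ± 0.09, or 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.773). The call for Otol1 was lost without any 1 library (adjusted p = 0.0777 to 0.262). Of 4 sex-linked genes, all on chromosome Y, 0 passed (1 higher at an unadjusted p under 0.05, none adjusted over the list alone). Their summed FPKM was 17.7, 28.3, 55.6 and 27.6 in wild-type replicates 2 and 3 and knockout replicates 2 and 3. Camera gave adjusted p = 0.174 for them, and 0.00257 without knockout replicate 3. Without knockout replicate 2 or 3, 0 genes of these lists were called.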

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

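The rescalings by median of ratios and to equal sums, the filter of 1 FPKM in at least 2 libraries and the pseudocount of 0.1 for lists were chosen after the data were seen; the other alternatives were planned. The 618 calls became 266 with no filter on low values (17615 genes tested), 98 at an adjusted p under 0.01 and 216 with a 2-fold minimum, and between 1 and 580 with 1 library left out, where a genotype with 1 library is assumed to vary like the other. Both values of 1 came from leaving out a knockout library, when the spread was estimated from the wild-type pair, whose log2 differences had an SD of 0.338 against 0.222 in the knockout pair. With the replicate number as a replicate block there were 2353 calls, which included all 618; deviations of libraries with the same number correlated at 0.4 over 2 pairs, and the labels do not say that the numbers mark shared animals or days. The other settings gave 598 to 706 calls. Of the 32 lists, 18 passed by camera, 0 with an estimated correlation, 7 with directional fry (6 of them among the 18), 25 with mixed fry (15 among the 18), and 14 to 18 under the settings that changed the filter, scaling, pseudocount, block or libraries (13 to 18 among the 18). By camera, the spiral ganglion list passed under the block and in no other of these settings (adjusted p = 0.0131, median -0.23, with 4 members called higher and 6 lower). Zbtb20 kept its log2 fold change of -0.49 but not its call with no filter, and ranged from -0.51 to -0.48 with adjusted p above the threshold with 1 library left out; the cause was not tested beyond the number of genes and libraries. Of 74 called genes named by the rule, 47 kept their call with no filter, 74 under the block, and 71 and 73 under the rescalings. No list past the threshold, by its camera direction, and no called gene named by the rule changed direction under these alternatives; those that did had not passed. The list for immature epithelium turned under the block (median -0.04) and with 1 library left out (-0.04 to 0.08). Those for strial basal cells (0 to 0.09), vestibular genes (0.18 to 0.21), spiral ganglion neurons (-0.42 to -0.12) and the tectorial membrane (-0.08 to 0.11) turned with 1 library left out and not under the block, and that for spiral ganglion neurons also under median of ratios (-0.29). The direction is that of camera relative to other genes, and the values are medians. With 1 library left out Gfap ranged from -0.02 to 0.32 and Ebf1 from -0.03 to 0.17, and Ebf1 was 0 under median of ratios; the cause was not tested. Tests that need counts (edgeR and DESeq2 with their size factors, a filter in CPM) were not run. Genes under a mean of 0.5 FPKM were not tested. Of simulated 2-fold changes in the more abundant genes 86.6% were called. Smaller changes, changes in low genes and other depths were not simulated, so what depth limits was not measured.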

Other observations

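All tests in this part were chosen after the result was seen, except that of choroid plexus genes and the count of called liver genes, which were set before the values of these genes were examined. Several gene families outside the fixed lists held called genes. Of 14 tested small leucine-rich proteoglycan genes, which encode collagen-binding matrix proteins, 4 rose and 1 fell (limma), or 8 and 1 adjusted over the list alone. Dcn, Kera, Fmod and Ogn rose by 1.83 ± 0.11, 1.24 ± 0.19, 0.98 ± 0.13 and 0.93 ± 0.15 (SE, n = 2 per group) on the log2 scale, and Chad fell by 0.88 ± 0.09. Of 21 imprinted genes, expressed from the copy of 1 parent, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. Peg3 was at 7.98 and 7.67 FPKM in the wild type and at 16.77 and 17.81 FPKM in the knockout, Mest, Plagl1 and Cdkn1c also rose, and Nnat, the neuronatin gene, fell by 1.24 ± 0.11. Of 30 carbonic anhydrase and SLC4 or SLC26 anion transporter genes 1 rose (Car9) and 6 fell, or 5 and 6 adjusted over the list alone. Those that fell included Slc4a10 (51.75 and 60.6 against 18.84 and 26.41 FPKM), Car12 (-1.15 ± 0.17), Car2 (-0.43 ± 0.08), and Slc4a1, Slc4a11 and Slc26a4 of the fixed lists. Dcn and Chad are also in fixed lists. Without knockout replicate 2 or 3, where Ttr was the 1 call among all genes, 0 of these genes were called.

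All 16 tested genes of peripheral myelin fell, with a median of -2.34. A difference in scale between libraries is argued against, since 16 of 16 were still called lower after median-of-ratios rescaling. Fewer Schwann cells of every stage may be the cause: 10 tested genes of the lineage outside the myelin program had a median of -0.94 (quartiles -1.38 and -0.6) and 6 were called lower (Art3, Sema3b, Foxd3, Ngfr, Erbb3 and Plekhb1), but the median stands above the bound of -1.17, midway between 0 and the myelin median, by less than the spread of the genes, and Sox10 (like Ngfr also in a fixed list, and expressed by strial cells) was at -0.15 ± 0.12. The pseudocount of 1 also shrinks the changes of low lineage genes more than those of the abundant myelin genes. Foxd3, for one, was at 4.32 and 2.97 FPKM in the wild type and 0.79 and 0.73 FPKM in the knockout, with -1.38. The side of the bound on which the median falls therefore decides nothing. Less nerve tissue may be too, as the spiral ganglion list had a median of -0.23 with quartiles of -1.42 and 0.66, and its members went both ways. These 2 explanations and lower myelin expression per Schwann cell after loss of Zbtb20, which was not tested, cannot be told apart with whole cochleae and 2 libraries per group.

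Among strial genes at a mean of 1 FPKM or more, 11 of 31 were called higher. A larger share of every other gene after loss of Schwann cell RNA is argued against, since all tested genes outside the myelin list had a median of 0.06 (quartiles -0.07 and 0.18) where the bound was 0.86, midway between 0 and the median of the strial genes called higher. A larger share of stria in the knockout libraries may be the cause, with 1 strial gene called lower, Kit, where 2 would have argued against it, while Slc12a2, abundant in marginal cells and also expressed elsewhere in the cochlea, was at 0.01 ± 0.11. That explanation and higher expression per strial cell after loss of Zbtb20, which was not tested, cannot be told apart, because no count of strial cells goes with the libraries.

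Ttr rose 34.4-fold, and the gene is abundant in choroid plexus and liver. Choroid plexus tissue in a share large enough to raise the genes of that tissue together is argued against, since the 14 tested genes of that tissue had a median of -0.01 (quartiles -0.27 and 0.25), 3 of them (Aqp1, Clic6 and Prlr) higher and 2 (Sostdc1 and Kl) lower, and Folr1 was at 1.3 and 1.72 FPKM in the wild type and 1.26 and 1.16 FPKM in the knockout. The median cannot exclude a small share, because members such as Igfbp2 (597.87 and 539.56 FPKM) were already high in the wild type. Liver tissue is argued against by the levels of abundant liver genes: in the 8 with a wild-type mean under 1 FPKM the median rise was 0.01 FPKM (quartiles -0.004 and 0.056, highest 0.26), beside 302.7 FPKM for Ttr, and Apoa1 was at 0.4 and 0.66 FPKM in the wild type and 0.68 and 0.26 FPKM in the knockout. A count of called liver genes, set as the test beforehand, decided nothing, since 4 of 9 with a value were tested (limma, 0 called, 0 at an unadjusted p under 0.05), Trf among them is high in all 4 libraries and Alb has no value here. Candidate explanations that remain are a small share of choroid plexus tissue and higher expression in cells of the cochlea after loss of Zbtb20. The latter is a hypothesis from the same data that was not tested.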
